A study of Homo sapiens with 6 samples.

How the data were processed

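Primary human decidual cells were measured on 6 Affymetrix Human Gene 2.0 ST arrays, 3 of cultures kept with vehicle and 3 of cultures kept with IL-1β for 6 h. The 3 arrays of each group are labelled as numbered biological replicates. The values were deposited as 1 table of normalized expression values per transcript cluster, and per the submitters' processing notes the Transcriptome Analysis Console was used, with no version given. The methods of background correction, summarization and normalization, and the base of the logarithm, are not given in the sources used here. The deposited values were taken as log2, because values from 1.24 to 14.5 on another common base would exceed the range of the scanner, and as normalized between arrays, because the 6 columns have near-equal quantiles. Array medians were at most 5.73. Pearson correlations between arrays across genes were 0.995 to 0.996 within groups and 0.978 to 0.982 between groups, and the SD of the difference between 2 arrays of a group was 0.176 to 0.208.

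The table had 53617 rows, of which 15 (Y-linked genes, X-inactivation transcripts and genes with no chromosome given) were removed to protect donors or for lack of a position, and 53602 were analysed. Only 16083 of these (30.0%) carried a gene symbol, each a single symbol, and the other 37519 were left out of the gene comparison because they have no name in the files used here. Symbols were matched to a RefSeq gene table of assembly GRCh38.p14, from which names, synonyms, biotypes and gene order were taken. Where a gene had several transcript clusters, as 778 did, the brightest was used, which left 14870 genes. Listed genes without a named row, IL6, IL1B and NFKBIA among them, were not analysed here. Signals of near-identical genes (the KRTAP, PSG, HSPA1, MT1 and CXCL2/CXCL3 families) are uncertain, because probes can read more than 1 of them.

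Cultures with IL-1β were compared with vehicle cultures in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, moderated statistics, n = 3 per group), and genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. Fold changes are differences of group means of the log2 values, and SDs are between cultures. For 30 gene lists written from background knowledge before the data were examined, camera (limma) compared each list of at least 5 measured genes with the other genes at a preset inter-gene correlation of 0.01, with adjustment over the lists. At the preset correlation the p of camera rests on the number of genes and not of cultures, so its size does not measure the spread between cultures. Members of a list were also counted after adjustment over that list alone. The alternative list tests were camera with an estimated correlation and fry. The p of fry tests whether a list's genes move on balance in 1 direction and its mixed p whether they move in either direction, and neither compares a list with other genes. Genes were named by a rule: the 15 largest increases and the 15 largest decreases among genes past the test whose groups did not overlap, and in each list up to 4 members past the test and up to 2 not past it. Genes outside that rule are said to be named after their values were seen.

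Vehicle and IL-1β arrays share the replicate numbers 1, 2 and 3. Deviations from the group means correlated at 0.34, 0.12 and 0.13 between same-numbered arrays, and at -0.23 to 0.13 between the others. Deviations within a group cancel out, so these correlations are tied to each other. The negative ones all involve an array of replicate 1 and largely follow from the 0.34, so they are no independent evidence of pairing. Vehicle replicate 3 and IL-1β replicate 2 correlated at 0.127, above the 0.117 of the arrays numbered 2, so the pairing of replicates 2 and 3 is uncertain. The numbers were taken to pair the arrays, from the data and not from a statement of the labels. A fit with a replicate block was therefore run as an alternative, and its value is given beside a list member or result whose call it changes. Members named only for such a change were chosen after their values were seen. Other alternatives were leaving out each array, another quantile normalization, centring each array on its median, leaving out the dimmest 40% of genes, the mean of a gene's clusters, a test of every row, eBayes with a trend and robust estimation, no variance moderation, array weights, and adjusted p thresholds of 0.01 and 0.1. Leaving out each same-numbered pair and centring on the median of the named genes were added after the data were seen.

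The tests were tried on simulated values with normal noise at each gene's SD within groups, with 200 of the 14870 genes changed. Of changes of 0.5, 1 and 2 on the log2 scale, 59.7%, 97.0% and 98.5% were called, and 7 of 14670 unchanged genes were called. With no list moved, 0 of 30 were called, and the chemokine list was called when it was moved by 1. The noise was drawn for each gene on its own, without correlation between genes or a replicate effect. How often camera calls lists of correlated genes was therefore not tried, and the correlation estimated for the cell cycle list was 0.50. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. The raw array files were not analysed here.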

Results

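RNA was measured in 6 cultures of primary human decidual cells, the stromal cells of the uterine lining as remodelled for pregnancy. The cells were decidual fibroblasts from term tissue, passaged to remove leukocytes and then primed for 13 days with estradiol and the progestin medroxyprogesterone acetate. In 3 of the cultures 1 ng/ml of interleukin-1β (IL-1β), a proinflammatory cytokine, was added for 6 h, and the other 3 received the albumin-containing saline vehicle for the same time. Each culture was hybridised to 1 Affymetrix Human Gene 2.0 ST array, which reads transcripts along their whole length. The deposited values were taken as log2 from their range, since the base of the logarithm is not given in the sources used here, and every fold change rests on that reading. Array medians were at most 5.73, and the number of arrays limits the precision of every value. A single comparison follows from this design, namely which transcripts differ between decidual cells kept with IL-1β and those kept with vehicle. It was made for 14870 named genes.

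Among the 14870 named genes, the 2 that rose most when IL-1β was added encode chemokines. CXCL10, a chemoattractant of T cells, was 149-fold higher, at a log2 value of 5.32 ± 0.07 with vehicle and 12.54 ± 0.11 with IL-1β (SD, n = 3), and CXCL8, which attracts neutrophils, was 60.4-fold higher, at 6.88 ± 0.07 and 12.79 ± 0.07 (SD, n = 3). BCL2A1, an inhibitor of apoptosis, rose 46.1-fold, PTGS2, the inducible enzyme of prostaglandin synthesis, 43.9-fold, and SELE, which encodes the adhesion molecule E-selectin, 38.3-fold. The lowest fold changes belonged to 2 keratin-associated protein genes, KRTAP1-5 (5.72-fold lower) and KRTAP2-3 (4.69-fold lower), and to FGF9, a fibroblast growth factor gene that was 4.66-fold lower. Of 30 gene lists fixed beforehand, camera called 11, all of them upward, and 7 of these with an estimated correlation. With the preset correlation it also called 5 to 8 lists in the 9 other ways of forming groups of 3 arrays, and with an estimated one 0. Those groups mix vehicle and IL-1β arrays and keep part of the IL-1β difference, so these counts are no measure of chance.

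Across the 14870 genes, 2606 passed limma's test at an adjusted p under 0.05, 1140 of them higher and 1466 lower with IL-1β. Increases were larger than decreases: the median log2 change was 0.52 among the higher genes and -0.39 among the lower ones, and of the 275 genes changed at least 2-fold, 225 were higher and 50 lower. Decreases made up 56.3% of all calls on the deposited scale and 47.0% when each array was centred on the median of the named genes (1302 higher, 1155 lower), a centring chosen after the data were seen that removed a difference of -0.03 between the groups. In all 2606 genes the 3 IL-1β values lay wholly above or wholly below the 3 vehicle values, which passing the test with 3 arrays per group nearly ensures. The same held for 36.3% of the genes tested, a share that includes the 2606, where chance gives 10%. The number of lower genes was 935 without vehicle replicate 2 (899 higher), 905 without vehicle replicate 3 (907 higher), 905 without IL-1β replicate 2 (870 higher) and 845 without IL-1β replicate 3 (857 higher). The last of these left 1702 genes changed in total. Decreases were thus no longer the majority without vehicle replicate 3 or IL-1β replicate 3. Counts at 2-fold moved little, from 272 to 289 without any 1 array.

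**Figure D1:**
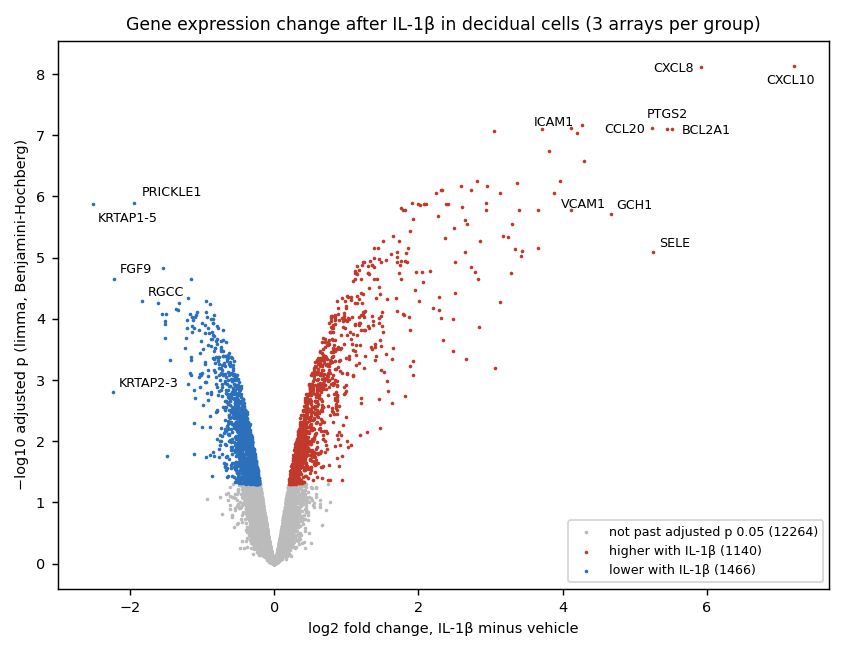
Each point is 1 of 14870 named genes, with its log2 change (IL-1β minus vehicle, 3 arrays per group) on the horizontal axis and the -log10 of its adjusted p from limma on the vertical axis. Red points are the 1140 higher genes and blue points the 1466 lower ones, and the right arm reaches 7.22 while the left arm ends at -2.52.

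Among the 15 named genes with the largest increases, CCL20 was higher by 5.25 on the log2 scale, and GCH1, the first enzyme of tetrahydrobiopterin synthesis, rose 25.5-fold. CCL5 rose 19.7-fold, ICAM1 19.2-fold and TSLP, an epithelial and stromal cytokine, 18.4-fold. CXCL6, CXCL11, KYNU (an enzyme of tryptophan breakdown), VCAM1 and CXCL5 rose 17.4-fold, 17.3-fold, 15.6-fold, 14.7-fold and 14.1-fold. Of these 15 genes 9, CXCL10, BCL2A1 and SELE among them, had vehicle means (3.70 to 5.52) under every array median, and no background level is given in the sources used here, so the size and rank of their folds are uncertain. SELE varied most between vehicle cultures (4.79 ± 0.56, SD, n = 3), and its adjusted p of 8.16e-06 was the highest of the 15. On the side of decreases, KRTAP1-5 went from 12.12 ± 0.06 to 9.60 ± 0.14 (SD, n = 3), a log2 change of -2.52 with a standard error of 0.08. PRICKLE1, a planar cell polarity gene, was 3.84-fold lower and RGCC, a regulator of the cell cycle, 3.55-fold lower. The noncoding RNA LINC01085, SERTAD4, the WNT receptor gene FZD2, STAMBPL1, the transcription factor gene OSR1 and ADM, which encodes the vasodilator adrenomedullin, fell to between 3.04-fold and 2.85-fold lower. CDC42EP3 was 2.82-fold, RTKN2 2.72-fold and JADE1 2.57-fold lower, and KRTAP4-12 was 2.81-fold lower but did not pass without vehicle replicate 1, IL-1β replicate 2 or IL-1β replicate 3 (adjusted p = 0.0576, 0.0641 and 0.0590). Values of the KRTAP genes are uncertain, because their sequences are close enough for probes to be shared.

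**Figure D2:**
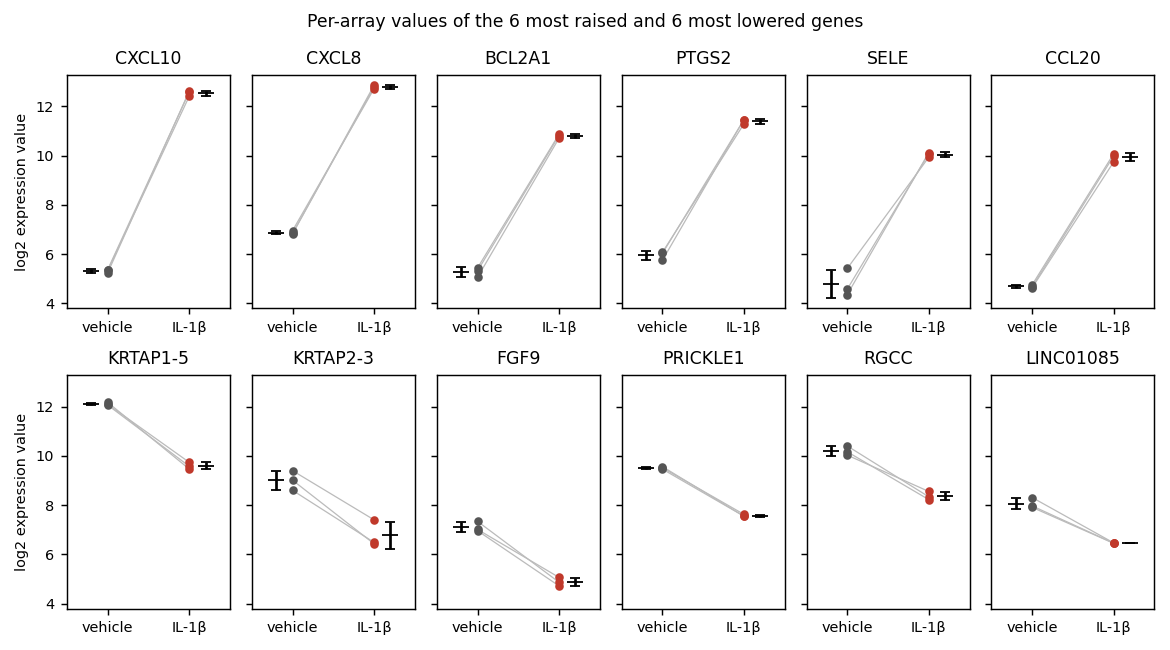
Log2 expression values of the 6 most raised named genes (top row) and the 6 most lowered named genes (bottom row), with 1 point per array. Grey lines join arrays of the same replicate number, and the mean ± SD of the 3 arrays is beside them. CXCL10 has vehicle values near 5.32 and IL-1β values near 12.54, and in every panel the groups are apart.

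Counts of list members refer to those with a named value, 478 of 786 summed over the lists. The share was lowest for the antigen presentation (6 of 20), oxidative phosphorylation (9 of 30) and matrix (12 of 30) lists, where most listed members were not tested. It was highest for the chemokine list (27 of 29). Of 27 measured chemokine genes, 14 rose, 0 fell and 13 did not pass, against 15 higher and 1 lower adjusted over the list alone, and the list shifted upward (camera adjusted p = 2.90e-15). PPBP (log2 change 0.10, SE 0.14) and CXCL9 (0.28, SE 0.09, adjusted p = 0.0686) were among those not past the test. The paired fit with a replicate block added CXCL12 as lower (-0.43, adjusted p = 0.0135). Of 29 listed cytokine genes 16 were measured, without IL6 and IL1B, and 14 of these were higher, the same number adjusted over the list alone (camera adjusted p = 1.02e-16). LIF, a cytokine of implantation, was 10.3-fold higher, the granulocyte growth factor gene CSF3 9.51-fold and IL11 6.66-fold, while IL10 (0.10) and IL16 (-0.16) did not pass. Adhesion genes shifted upward too (camera adjusted p = 6.09e-05), with 5 of 12 higher and 7 adjusted over the list alone. Besides SELE, ICAM1 and VCAM1 these were ALCAM (1.80-fold) and CD44 (1.51-fold, named after its value was seen). ICAM2 (0.01) and ICAM3 (-0.17) did not pass, and neither did JAM2 (0.58), which passed with the replicate block (adjusted p = 0.00405) and without IL-1β replicate 1 (adjusted p = 0.0356).

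The signalling route downstream of IL-1β showed the same direction. Of 17 measured NF-κB subunit and feedback genes, out of 30 listed and without the inhibitor gene NFKBIA, 15 rose and 0 fell (16 higher adjusted over the list alone, camera adjusted p = 9.55e-21). REL and NFKB1, 2 of the subunits, were 10.1-fold and 7.02-fold higher, the kinase gene MAP3K8 8.76-fold and the inhibitor TNIP3 7.76-fold, while MAP3K14 (-0.07) did not pass. In the IL-1 and Toll-like receptor list 7 of 21 genes rose and 0 fell, with 9 higher adjusted over the list alone (camera adjusted p = 3.51e-06). They included the adaptor kinase gene IRAK2 (8.27-fold), the inhibitory IRAK3 (2.81-fold) and the receptor antagonist gene IL1RN (2.26-fold), whereas IL1RL1 (0.09) and the adaptor gene MYD88 (0.28) did not pass, the latter at adjusted p = 0.0512, against 0.0391 with the replicate block and 0.0428 without vehicle replicate 1. Immediate-early genes and MAP kinase phosphatases went both ways, with 13 of 25 higher, 2 lower and 10 not past (16 and 2 adjusted over the list alone). Their upward shift had a camera adjusted p of 2.40e-07, and an adjusted p = 0.0741 with an estimated correlation. The phosphatase genes DUSP5 and DUSP1 rose 4.99-fold and 2.34-fold, ATF3 2.81-fold and IER3 2.59-fold. Both lower members, named after their values were seen, encode zinc finger transcription factors: EGR1 was 2.28-fold and KLF4 1.32-fold lower. JUND (0.08) did not pass.

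Interferon-induced genes rose as a group, with 17 of 20 higher, 0 lower and a camera adjusted p of 3.31e-21 (19 higher adjusted over the list alone). With an estimated correlation the camera adjusted p was 0.00863. IFI44 was 8.99-fold higher, the RNA sensor genes IFIH1 and RIGI 5.17-fold and 4.32-fold, and the antiviral RSAD2 4.07-fold. IRF3 (0.12) did not pass, and neither did ISG15 (0.31, adjusted p = 0.132), which passed in the paired fit with a replicate block (adjusted p = 0.0216). Antigen presentation was represented by 6 genes, of which 3 rose and 0 fell (4 higher adjusted over the list alone). The list's camera adjusted p was 0.000648, with an adjusted p = 0.0641 with an estimated correlation. Of its movers TAPBP (1.45-fold) serves peptide loading, but CD274 (6.07-fold) and PDCD1LG2 (1.28-fold) encode ligands of the inhibitory receptor PD-1, and B2M (0.01) did not pass. The peptidase genes ERAP1 (0.45) and ERAP2 (0.43) passed with the replicate block (adjusted p = 0.00701 and 0.0439), the first also without IL-1β replicate 1 (adjusted p = 0.0307). Complement genes were split, with 3 of 13 higher, 1 lower and 9 not past (3 and 2 adjusted over the list alone, camera adjusted p = 0.0792). C3, the central component, was 7.64-fold and CFB 5.66-fold higher, and C2 (0.08) did not pass. C3AR1 (1.68-fold higher) was lost without vehicle replicate 1 or 3 or IL-1β replicate 2 or 3 (adjusted p = 0.114 to 0.125), and MASP1 (1.26-fold lower) without vehicle replicate 2 (adjusted p = 0.0540). The complement list itself passed without vehicle replicate 2, vehicle replicate 3 or IL-1β replicate 1 (camera adjusted p = 0.0380, 0.0462 and 0.0196).

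Genes regulating apoptosis rose on both sides of that process, with 12 of 15 higher, 0 lower and 13 higher adjusted over the list alone (camera adjusted p = 2.87e-12). Beside the inhibitors BCL2A1 and CFLAR (2.66-fold higher), the kinase gene RIPK2 was 4.74-fold and the pro-apoptotic BCL2L11 3.79-fold higher, while BAX (-0.06) and BAD (-0.15) did not pass. In the insulin-like and epidermal growth factor list, 6 of 18 genes rose and 1 fell, also when adjusted over the list alone. Its shift had a camera adjusted p of 0.000341, and an adjusted p = 0.0523 with an estimated correlation. EREG was 13.1-fold, HBEGF 4.03-fold and NRG1 3.69-fold higher, all ligands of the epidermal growth factor receptor family, and the signalling inhibitor gene SPRY4 1.85-fold. ERRFI1, another inhibitor, named after its value was seen, was 1.24-fold lower and did not pass without vehicle replicate 3 or IL-1β replicate 2 (adjusted p = 0.0555 and 0.0569). IGF1 (0.17) and IGF1R (0.01) did not pass.

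Markers and regulators of decidualization shifted upward at the preset correlation (camera adjusted p = 0.00862) but did not pass with an estimated one (camera adjusted p = 0.233). The median log2 change of the list was 0.08 and its mean 0.32, so the shift rested on a few members. Of 18 measured genes 6 rose, 1 fell and 11 did not pass, against 7 and 2 adjusted over the list alone. The signal transducer gene STAT5A was 6.64-fold, the cytokine gene IL15 2.63-fold and the morphogen gene BMP2 1.70-fold higher. Named after their values were seen, STAT5B and STAT3 were 1.48-fold and 1.28-fold higher, and the hormone gene SST was 1.25-fold higher, a call lost without any 1 of the 6 arrays (adjusted p = 0.0579 to 0.124). HAND2, a transcription factor of progesterone-primed stroma, was 1.65-fold lower. The classical markers PRL (3.58 ± 0.29 with vehicle, 3.66 ± 0.19 with IL-1β, SD, n = 3) and IGFBP1 (5.46 ± 0.14 and 5.39 ± 0.14, SD, n = 3) did not pass, at adjusted p = 0.796 and 0.709, but both lay under the array medians, so that a lack of change cannot be read from them. MAOB (0.29) passed with the replicate block (adjusted p = 0.0234) but not without it.

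Steroid hormone genes did not pass as a list (camera adjusted p = 0.949), with 2 of 13 higher and 2 lower (2 and 3 adjusted over the list alone). HSD11B1, which regenerates cortisol, rose 2.40-fold and the clock gene PER1 2.02-fold, and the coactivator gene NCOA2 and PGRMC2 were 1.63-fold and 1.42-fold lower, while the progesterone receptor gene PGR (-0.05) did not pass. Prostaglandin genes had 4 of 17 members higher and 0 lower (4 and 1 adjusted over the list alone), with a camera adjusted p of 0.0874. Besides PTGS2 these were PTGES, a terminal synthase of prostaglandin E2 (2.12-fold), and the receptor genes PTGER3 (1.83-fold) and PTGFR (1.39-fold, lost without IL-1β replicate 3 at an adjusted p of 0.0525). PTGES2 (-0.10) did not pass. Nor did PTGS1 (-0.25, adjusted p = 0.160), the constitutive isoform, except in the paired fit with a replicate block (adjusted p = 0.0419), where PTGIS (-0.36, adjusted p = 0.0469) and PTGDS (-0.25, adjusted p = 0.0434) also passed, so that 3 members were lower. PTGIS also passed without vehicle replicate 1 (adjusted p = 0.0217). Contraction-associated genes went both ways, 4 of 13 higher and 3 lower, also adjusted over the list alone (camera adjusted p = 0.542). EDNRB, an endothelin receptor gene, was 8.32-fold and the endothelin gene EDN1 1.76-fold higher, and RGS4, a brake on receptor signalling, 2.28-fold lower. Named after their values were seen, the smooth muscle genes MYLK and CALD1 were 1.23-fold and 1.20-fold lower, and the second of these calls was lost without any 1 of the 6 arrays (adjusted p = 0.0599 to 0.105). OXTR, the oxytocin receptor gene, did not pass (0.09, SE 0.09).

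Proteases and their inhibitors included 4 of 14 higher and 2 lower genes (5 and 3 adjusted over the list alone, camera adjusted p = 0.0886). The metalloproteinase genes MMP12, MMP10 and MMP1 rose 12.6-fold, 4.99-fold and 3.13-fold. MMP8 (1.49-fold higher) did not pass without vehicle replicate 2, vehicle replicate 3 or IL-1β replicate 3 (adjusted p = 0.0592 to 0.0764). MMP16 and TIMP4, named after their values were seen, were 1.37-fold and 1.33-fold lower. MMP16 was lost in the paired fit with a replicate block (adjusted p = 0.0636) and without any 1 array except vehicle replicate 1 (0.0576 to 0.106), and TIMP4 without any 1 array except vehicle replicate 2 (0.0608 to 0.0988). Among 12 matrix genes only TNC, for tenascin, passed (2.28-fold higher, also adjusted over the list alone, camera adjusted p = 0.744), though not without variance moderation (adjusted p = 0.0836) or without both arrays of replicate 3 (adjusted p = 0.0542), and FN1 (-0.05) and ELN (0.02) did not. Coagulation and vascular genes had 6 of 18 higher and 2 lower (6 and 4 adjusted over the list alone, camera adjusted p = 0.232). HGF was 4.63-fold, VEGFA 1.83-fold, FLT1 1.76-fold and ANGPTL4 1.54-fold higher, and ANGPT1 and F2R, named after their values were seen, 1.43-fold and 1.24-fold lower. Another of the 6, VEGFC (0.27), was lost with the replicate block (adjusted p = 0.0570) and without any 1 of the 6 arrays (adjusted p = 0.0557 to 0.0881). In the WNT, BMP and TGF-β list 6 of 23 genes rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.737). The antagonist gene BAMBI was 3.27-fold higher, GDF15 2.18-fold, the WNT receptor gene FZD7 2.04-fold and the WNT antagonist gene DKK1 2.02-fold lower, and WNT2 (0.16) did not pass.

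Of 27 cell cycle genes 0 rose and 2 fell, also adjusted over the list alone, namely the replication helicase genes MCM6 (1.35-fold lower) and MCM3 (1.27-fold lower), while MKI67 (0.10) and TOP2A (0.11) did not pass. The mitotic genes CDC20 (-0.38) and KIF20A (-0.32) passed as lower with the replicate block (adjusted p = 0.0136 and 0.0242), which made 4. The list had a camera adjusted p of 0.239, and 0.0131 without IL-1β replicate 1, when it passed downward. Of 30 listed oxidative phosphorylation genes 9 were measured. None of these passed limma's test, adjusted over all genes or adjusted over the list alone, and 0 had an unadjusted p under 0.05 (UQCRC1 -0.01, UQCRC2 -0.07, camera adjusted p = 0.744). Glycolysis and hypoxia genes had HK2 as the 1 higher (1.69-fold) and ADM as the 1 lower of 12, also adjusted over the list alone (camera adjusted p = 0.586), and HK1 (0.09) and GPI (-0.10) did not pass. Unfolded protein response genes split, with 4 of 15 higher and 2 lower (4 and 3 adjusted over the list alone, camera adjusted p = 0.679). The stress sensor genes ERN1 and EIF2AK3 were 2.08-fold and 1.51-fold higher, while DDIT3 and TRIB3, targets of the same response, were 2.20-fold and 2.06-fold lower. Named after their values were seen, XBP1 was 1.43-fold and SDF2L1 1.27-fold higher, the latter not without IL-1β replicate 3 (adjusted p = 0.0503). The replicate block added ATF4 (-0.23), DDIT4 (-0.29) and ASNS (-0.32) as lower, at adjusted p = 0.0494, 0.0222 and 0.0229, which made 5. Cholesterol genes had 3 of 18 higher and 2 lower (3 and 5 adjusted over the list alone, camera adjusted p = 0.679). INSIG1, a feedback inhibitor, was 3.26-fold, STARD4 1.55-fold and HMGCS1, named after its value was seen, 1.33-fold higher, HSD17B7 and MVK were 1.46-fold and 1.43-fold lower, and SQLE (0.09) did not pass, nor did EBP (-0.26), which passed as lower with the replicate block (adjusted p = 0.0401). Antioxidant and metal-handling genes had 3 of 16 higher and 1 lower (6 and 1 adjusted over the list alone, camera adjusted p = 0.239). GPX3 was 1.54-fold higher. Calls of the other 3 were lost when arrays were left out: MT1X (1.20-fold higher) without vehicle replicate 2 or 3 or IL-1β replicate 1 or 3 (adjusted p = 0.0514 to 0.0695), TXNRD1 (1.19-fold higher) without any 1 of the 6 (0.0501 to 0.0700) and CAT (1.24-fold lower) without vehicle replicate 1 or 2 or IL-1β replicate 2 or 3 (0.0587 to 0.0751). The replicate block added HMOX1 (0.37), MT1E (0.57) and MT2A (0.25) as higher (adjusted p = 0.0193, 0.00595 and 0.0386), which made 6, and HMOX1 also passed without vehicle replicate 1 (0.0309) and MT1E without IL-1β replicate 2 (0.0248).

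None of 5 lists of markers of other cell types that the cultures could hold passed camera, which compares a list with the other genes, but fry, which does not, called the leukocyte and trophoblast markers upward (adjusted p = 0.0309 and 0.0124) and the smooth muscle markers downward (adjusted p = 0.0237). Leukocyte markers had a mean log2 level of 6.27 in both groups, taken as the median of 13 genes per array, with an SD of 0.13 for vehicle and 0.17 for IL-1β (n = 3). Only LCP1, an actin-bundling protein gene, rose among them (3.51-fold, also adjusted over the list alone, camera adjusted p = 0.219), while CD2 (0.17) and CD8A (0.09) did not pass. Trophoblast markers had 2 of 10 higher, TFAP2C (1.79-fold) and EGFR (1.80-fold), and 1 lower, PSG3 (log2 change -0.58), with 3 and 1 adjusted over the list alone (camera adjusted p = 0.239). KRT7 (0.03) and CSH1 (-0.01) did not pass. Of 14 endothelial markers FLT1 rose, also adjusted over the list alone (camera adjusted p = 0.756), and PECAM1 (0.18) and VWF (-0.10) did not pass. Epithelial markers had KRT18 lower (log2 change -0.59) and PAX8 higher (1.26-fold) of 15, also adjusted over the list alone (camera adjusted p = 0.679), and PAX8 was lost without any 1 array except vehicle replicate 3 (adjusted p = 0.0680 to 0.114). EPCAM (-0.05) and KRT8 (-0.16) did not pass. In these 3 lists the replicate block added GCM1 (0.26) and LYVE1 (0.29) as higher and KRT19 (-0.51) as lower (adjusted p = 0.0332, 0.0475 and 0.00800), and each also passed without 1 array, namely IL-1β replicate 3, vehicle replicate 3 and IL-1β replicate 1 (adjusted p = 0.04997, 0.0339 and 0.0465). Smooth muscle and pericyte markers stood at 8.02 ± 0.13 with vehicle and 7.69 ± 0.21 with IL-1β (SD, n = 3, medians of 11 genes), and the 3 differences within same-numbered pairs were -0.24, -0.37 and -0.38. In the paired fit with a replicate block the list's fry adjusted p was 0.160, while its member DES (-0.40, adjusted p = 0.0915) passed as lower (adjusted p = 0.0273), as it did without IL-1β replicate 1 (adjusted p = 0.0119). MYOCD was 2.37-fold higher, LMOD1 1.89-fold and PLN 1.51-fold lower, against 1 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.494), and SMTN (0.17) did not pass.

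**Figure D3:**
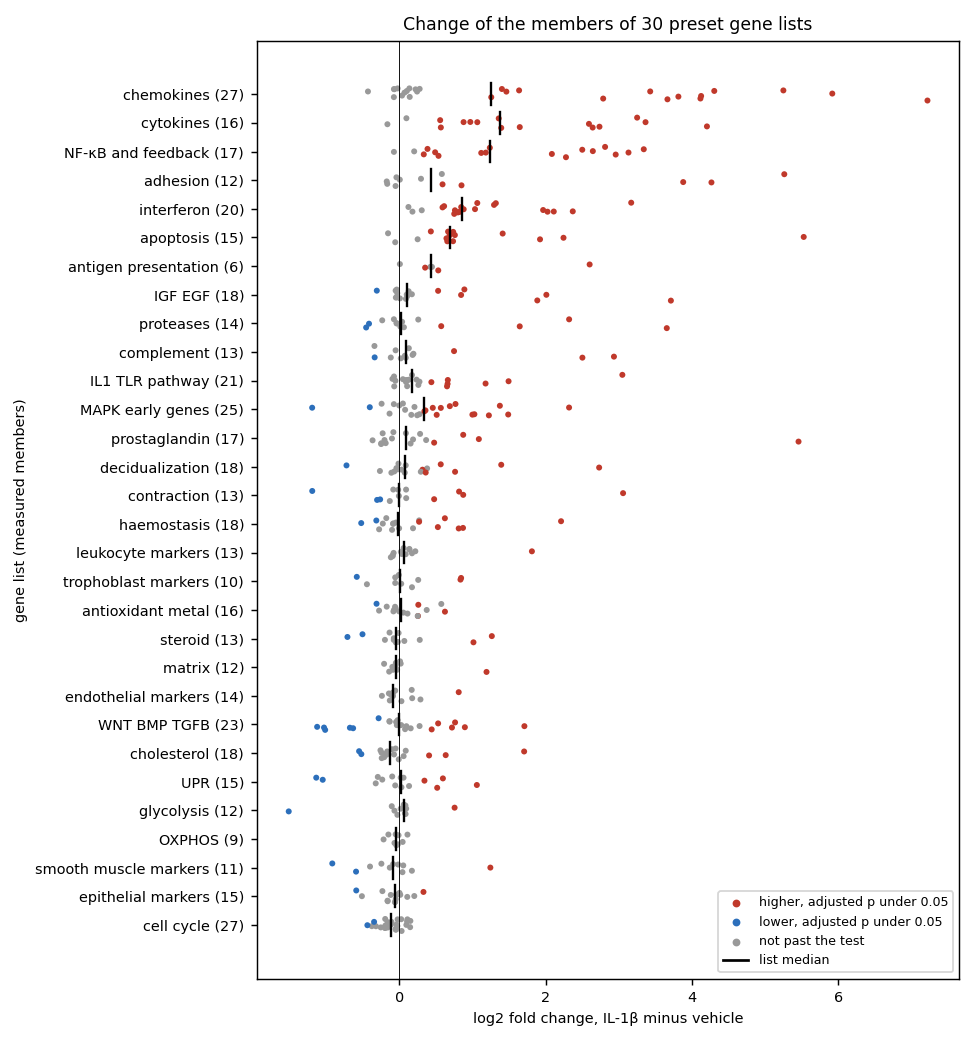
Log2 change (IL-1β minus vehicle) of each measured member of the 30 gene lists, with the number measured in parentheses, red and blue points for members higher and lower at an adjusted p under 0.05 (limma, 3 arrays per group), grey points for members not past the test, and a black bar at the list median. The cytokine, chemokine and NF-κB medians lie at 1.38, 1.26 and 1.24, and the median of the oxidative phosphorylation list is -0.04.

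For 9 lists, none of them past the test, the median, the mean and the direction of the test differed in sign. The test pointed up with medians below 0 and means above 0 for the contraction (-0.0056 and 0.26), coagulation and vascular (-0.02 and 0.22), WNT, BMP and TGF-β (-0.00013 and 0.03) and endothelial (-0.08 and 0.03) lists. It pointed up with medians above 0 and means below 0 for the unfolded protein response (0.02 and -0.03) and glycolysis (0.07 and -0.04) lists. It pointed down with medians below 0 and means above 0 for the matrix (-0.05 and 0.04), steroid (-0.05 and 0.07) and cholesterol (-0.13 and 0.01) lists. Of the 11 lists past the test, 7 also passed with an estimated correlation, namely the chemokine, cytokine, IL-1 and Toll-like receptor, NF-κB, adhesion, interferon and apoptosis lists. Their camera adjusted p was then 0.00863 for the cytokine, NF-κB and interferon lists and 0.0149 for the chemokine and apoptosis lists. It was 0.0284 for the IL-1 and Toll-like receptor list and 0.0449 for the adhesion list.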

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

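Every test in this part was chosen before its result was seen. Transcript clusters without a gene name were not used in the comparison above, and a signal was present in them: 775 were higher and 700 lower with IL-1β at an adjusted p under 0.05 (limma, n = 3 per group), 225 of them at least 2-fold higher and 77 at least 2-fold lower. As a share of the unnamed clusters 3.93% changed, and their median level was 5.31, against 6.79 for the named genes. Named after their values were seen, cluster 16901974 went from 5.11 to 11.13 (65.1-fold higher) and cluster 17070242 from 4.29 to 9.32 (32.6-fold higher), while cluster 17052060 (4.06-fold lower) and cluster 16766907 (4.54-fold lower) had large decreases. Cluster 16901974 thus rose more than CXCL8 (60.4-fold), so the rankings given above hold only among named genes. The transcripts that these clusters read were not identified here.

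With 3 arrays per group there are 10 splits of the 6 arrays, so the share of splits with a result as large as the real one cannot be under 0.05. For the 2606 genes changed it was 1 of 10, with a highest other value of 0 (limma, 245 to 675 genes at an unadjusted p under 0.05 in the others, 4587 in the real split). For the 275 genes changed at least 2-fold it was also 1 of 10, with a highest other value of 0. For the 11 lists shifted it was again 1 of 10, with a highest other value of 8. Of the 9 other splits, 3 part all same-numbered pairs as the real split does, and they gave 0 genes (limma, 245 to 282 at an unadjusted p under 0.05) and 5 to 8 lists. Every other split mixes vehicle and IL-1β arrays in its groups, which puts much of the IL-1β difference into the spread within groups. A low count of genes there was nearly fixed in advance. Part of the difference also remains between such groups, so the counts of the other splits are no measure of chance.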

How the results depend on the processing

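Leaving out same-numbered pairs and centring on the median of the named genes were chosen after the data were seen. The counts at 2-fold were the steadiest: 275 genes (225 higher, 50 lower) became 271 to 289 when 1 array or 1 pair was left out, and 247 to 284 under the other settings except a test of every row, which takes in the unnamed clusters and gave 601 (475 higher, 126 lower). The count of all changed genes depended on which arrays were left out, with 1702 (without IL-1β replicate 3) to 2275 without 1 array and 977 to 1954 without 1 pair (higher 593 to 1035, lower 384 to 1240 over both). The 1954 came without the pair of replicate 1, whose arrays had the lowest array weights (0.64 for vehicle, 0.70 for IL-1β). That was more than without any 1 array of replicates 2 and 3 (1702 to 1834). Lower genes numbered 845 to 935 without vehicle replicate 2 or 3 or IL-1β replicate 2 or 3, and higher genes 857 to 907. Without the pair of replicate 2 the count of changed genes was 1029 (613 higher, 416 lower) and without that of replicate 3 977, where 2 arrays remain per group. Without variance moderation 906 genes were lower (848 higher), and at an adjusted p under 0.01 the counts were 1279 changed, 704 higher and 575 lower. Centring on the median of the named genes gave 2457 changed genes, of which 47.0% were lower, against 56.3% of the 2606, and a test of every row gave 1562 higher and 1358 lower. In the paired fit with a replicate block 2889 genes changed (1216 higher, 1673 lower), 2409 of them also called without it, with the same 275 at 2-fold and 11 lists. Among list members the block added 23 calls and lost 2 (MMP16 and VEGFC), each given beside its list, and it changed no other call of a named gene or of a list by camera, while by fry the smooth muscle list was lost (adjusted p = 0.160). The 11 lists shifted became 11 to 13 without 1 array, where complement and cell cycle passed, 7 with an estimated correlation, 18 with fry and 17 with fry and a replicate block. Of 238 named genes 160 passed the test, 33 of these lost the call under at least 1 setting, and 0 turned direction. The calls of ANGPT1, F2R, GPX3, HMGCS1, KLF4, MCM3, MCM6, MYLK, PDCD1LG2, PSG3, STAT3, STAT5B, TFAP2C and TNC were lost without 1 or more pairs (adjusted p = 0.0529 to 0.128), and 17 named genes lost the call without variance moderation (0.0506 to 0.183), among them EDN1, STAT5B, TFAP2C and TNC, which kept it without any 1 array. The median signal of the unnamed clusters (5.31) against named genes (6.79) limits what can be read in dim transcripts.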

Other observations

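The test of leukocyte markers, the ratio among genes under a vehicle mean of 8 and the count of neighbours within 1 gene family were chosen after the results were seen, and so were all genes named in this paragraph. Noncoding transcripts changed as well: of 1394 long noncoding RNA genes 47 rose and 130 fell, and of 1072 microRNA genes 50 rose and 33 fell. The clusters of MIR146A and MIR155, microRNA genes known as targets of NF-κB, were 8.76-fold and 4.89-fold higher, and those of MIR503 and MIR424, neighbours in 1 precursor cluster, 2.34-fold and 2.20-fold lower. These clusters read the gene's transcript and not the mature microRNA. The long noncoding WAKMAR2 and LINC00473 were 3.81-fold and 2.77-fold higher, and SBF2-AS1 was 2.35-fold lower. Of protein-coding genes outside the lists, ELOVL7 (fatty acid elongation) was 10.8-fold, CTSS (cathepsin S) 9.83-fold, MFSD2A (a lipid transporter) 7.68-fold, RSPO3 (a WNT agonist) 5.58-fold, CLDN1 (a tight junction protein) 5.05-fold and KDM6B (a histone demethylase) 4.49-fold higher. TXNIP, an inhibitor of thioredoxin, was 2.31-fold lower, the kinase gene WEE1 2.14-fold and the transcription factor gene FOXL2 2.12-fold.

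Decreases under 2-fold outnumbered such increases (1416 and 915) while 2-fold increases outnumbered 2-fold decreases, but without both arrays of replicate 2 or of replicate 3 the first part turned (369 and 382, 338 and 368). A signal floor, which would keep dim genes from falling 2-fold, is argued against as the whole cause by genes with a vehicle mean of at least 8, where 75 were 2-fold higher and 28 lower, a ratio of 2.68 (95% bounds 1.71 to 4.30). Under that mean the ratio was 6.82 (150 and 22, bounds 4.34 to 11.2), and there a floor may add to the excess but cannot be told apart from genes silent with vehicle, because no background level was measured. Scaling between arrays, in which strongly raised genes could push the others down, cannot be told apart from small true decreases: with arrays centred on the median of the named genes, 78.8% of the 1466 lower genes were still called, but decreases and increases under 2-fold came to 1111 and 1062. No biological explanation was tested.

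Genes raised at least 2-fold lay next to each other in the order of the named genes more often than random genes, with 22 neighbouring pairs among 225 genes against 3.41 expected (7 at the upper bound of random sets, one-sided permutation p = 0.0001, the smallest that 10000 draws can give). Only the 14870 named genes were ordered, so genes without a named row can lie between the members of a pair. Overlap of the annotated genes is argued against, since 22 pairs had no overlapping bodies. A transcript that runs through both genes of a pair cannot be excluded by this, because transcript structure was not examined. A family was taken as the genes whose symbols share the letters before any digit, so it was set by name and not by sequence. Families so defined are argued against as the whole cause, though narrowly. With 1 raised gene kept per family, 6 pairs were left among 176 genes against 2.05 expected (5 at that bound, one-sided permutation p = 0.02). Among these pairs were RASSF8 with SSPN and RIPK2 with OSGIN2. Relatives with unlike symbols were not removed. For the 12 pairs within 1 family, such as CXCL10 with CXCL11 and HSPA1A with HSPA1B, signal shared between similar sequences cannot be told apart from a shared response, because no probe sequences were examined. Shared regulation of neighbours may account for the pairs of unlike genes, but it was not tested.

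Interferon-induced genes rose together, by a median of 0.86 (95% bootstrap interval 0.76 to 1.31). A gain of leukocytes large enough to raise most of 13 leukocyte markers is argued against by their median change of 0.060 (interval -0.08 to 0.14). A smaller gain cannot be excluded, because fry called the list upward (adjusted p = 0.0309), LCP1 rose by 1.81 and only 3 of the 13 lay above the median gene with vehicle. Both intervals resample the genes of a list and do not measure the spread between cultures. A response of 1 culture with IL-1β alone is argued against by the same-numbered pairs, in which the list's median difference was at least 0.90. That difference largely follows from the groups lying apart in the 17 of 20 members that passed, so it is no independent support. Donors were not compared, because the labels do not say that a replicate number marks a donor. A response of the decidual cells to IL-1β may account for the rise, as a hypothesis found and tested on the same data.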
